A study of Mus musculus with 16 samples.

How the data were processed

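RNA sequencing had been done on 16 libraries of the mouse melanoma line B16F10, carried as the derived lines B16F10-TDM and B16F10-TDMa. The labels do not say what these names stand for. Each line had been transduced with a scramble sgRNA (sgScramble) or an sgRNA targeting Nlrc5 (sgNlrc5). TDM culture and TDMa culture had 2 libraries per guide, and TDMa tumours had 4 per guide. Per the labels' protocols, cells grew in DMEM with fetal bovine serum, RNA was taken with Sepasol, and libraries were made from total RNA with the NEBNext Ultra II Directional kit, which keeps strand.

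The deposited values were log2 of a count divided by the sample's size factor, plus 1, per the file headers and the labels, with 1 table for each of TDM culture, TDMa culture and TDMa tumours. The submitters' processing notes name FastQC 0.12.0, STAR 2.7.10a, DESeq2 1.36.0 and the builds GRCm39 and mm39, without roles. The annotation, the counting tool, its strand setting and the filter on listed genes were not given in the sources used here. The tables listed 13143, 13284 and 14933 genes. The reference annotation at hand used an earlier build, so no coordinates were used, and symbols were taken from the tables. Of the listed identifiers, 13114, 13252 and 14891 matched that reference.

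The low values of each library were whole multiples of 1 step: 100% of values up to 2000 multiples lay within 0.1 of a whole read. Reads were recovered from these steps, giving between 12183889 and 16390886 reads per library over the listed genes, which is not the full library size. A listed gene had at least 20 reads summed over a culture table and 40 over the tumour table. A count of 0 was bounded by 3 reads summed over the group, and a ratio resting on 1 to 3 reads was given a 95% interval. Intervals and bounds cover counting error only.

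Each table was fitted alone, because each had been normalised alone. Values were put back on the count scale, and genes with a mean normalised count of at least 10 were kept: 11989, 12138 and 13385 genes. The fit was limma 3.58.1 (R 4.3.3) on log2(normalised count + 1), with variances moderated along an intensity trend, sgNlrc5 minus sgScramble, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. An error after a log2 fold change is a standard error, and one after a mean normalised count is a standard deviation. Differences between the lines, and between TDMa tumours and TDMa culture, were limma interaction terms with an intercept per group of each table and array weights that let the spread differ between tables. Overlaps of called genes were tested with Fisher's exact test, two-sided, beside the number that independent sets would share.

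Before the data were examined, 35 gene lists were fixed, along with the comparisons, the alternatives and the rule for named genes. The lists held MHC class I heavy chains with B2m, class I genes reported to depend on NLRC5, class I antigen processing, MHC class II, type I interferon and interferon gamma responses, genomic neighbours of Nlrc5 and other NLR genes. They also held methylation-silenced germline genes, imprinted genes, DNA methylation machinery, melanocyte lineage, proliferation, hypoxia and glycolysis, the unfolded protein and integrated stress response, immediate early genes, heat shock, mitochondrially encoded genes, p53 targets, cholesterol synthesis, and NF-kB with chemokines. Cell type lists covered T cells, cytotoxic effectors, T cell checkpoints, NK cells, B cells, macrophages, dendritic cells, neutrophils, fibroblasts, endothelium, skeletal muscle, keratinocytes, adipocytes and erythroid cells. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of that comparison. Camera with an estimated correlation and fry were run beside it.

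The genes named were Nlrc5, the tested class I members, up to 8 genes per direction with the largest called change, and up to 4 members of each other list with the smallest p. The 8 had separate groups and a mean normalised count of at least 50 in 1 group. Predicted genes were counted and not named.

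The fits were tested on simulated counts with known changes. In 12017 genes simulated after TDM culture, 84.8% of changes of log2 0.5, 95.5% of log2 1 and 100% of log2 2 were called, with 12 false calls among 199. After TDMa culture, with 12152 genes, the shares were 86.4%, 92.5% and 100%, with 14 false calls among 200. After TDMa tumours, with 13402 genes, they were 84.8%, 97% and 100%, with 10 false calls among 198. The interaction between lines recovered 94% of differences of log2 1 in 11470 genes, with 9 false calls among 202, and that between tumour and culture 93% in 11765 genes, with 16 false calls among 209. No list was called without a simulated shift. Genes were simulated independently of each other, so this could not show false list calls that arise from correlated members. All genes of a table also shared 1 relative spread, so the simulation could not test calls that rest on the intensity trend.

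Alternatives were other pseudocounts (0.5 and 10), no filter, a mean of at least 50, quantile normalisation, equal sums of normalised counts, no intensity trend, sample weights, the replicate number as a block, limma voom on the recovered reads, 1 spread for both tables, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Limma voom was the only count model run on the recovered reads, and no quasi-likelihood test was run.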

Results

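Gene expression was profiled in 16 libraries of B16F10 mouse melanoma, grown in culture or taken as tumours. Cells of the TDM and TDMa lines carried sgScramble or sgNlrc5, with 2 libraries per guide in each culture group and 4 per guide in TDMa tumours. Nlrc5 encodes a transactivator of MHC class I genes, and the series title names demethylation and activation of Nlrc5 and MHC class I as its subject. The recovered reads ran from 12183889 to 16390886 per library. The 10 most abundant genes took 5.57% to 6.25% of these reads in culture and 9.34% to 14.1% in tumours. The labels do not say whether replicates were separate cultures or animals, so p-values measure the spread between these samples.

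Nlrc5 (ENSMUSG00000074151), the targeted gene, was higher with sgNlrc5 in each group. In TDM culture it rose from 17.8 ± 7.22 to 68.0 ± 15.0 normalised counts (SD, n = 2 and 2), a log2 fold change of 1.91 ± 0.34 (limma adjusted p = 0.012). In TDMa culture it rose from 248 to 3144 normalised counts, by log2 3.66 ± 0.061 (adjusted p = 5.3e-18). In TDMa tumours it rose from 577 ± 243 to 3916 ± 445 (n = 4 and 4), by log2 2.88 ± 0.28 (adjusted p = 3.1e-05). The sgNlrc5 libraries lay above every sgScramble library of their group. The TDM value rests on few reads, and its call ended without sgNlrc5 replicate 2 (1.69, adjusted p = 0.087) and without the intensity trend (adjusted p = 0.38).

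**Figure D1:**
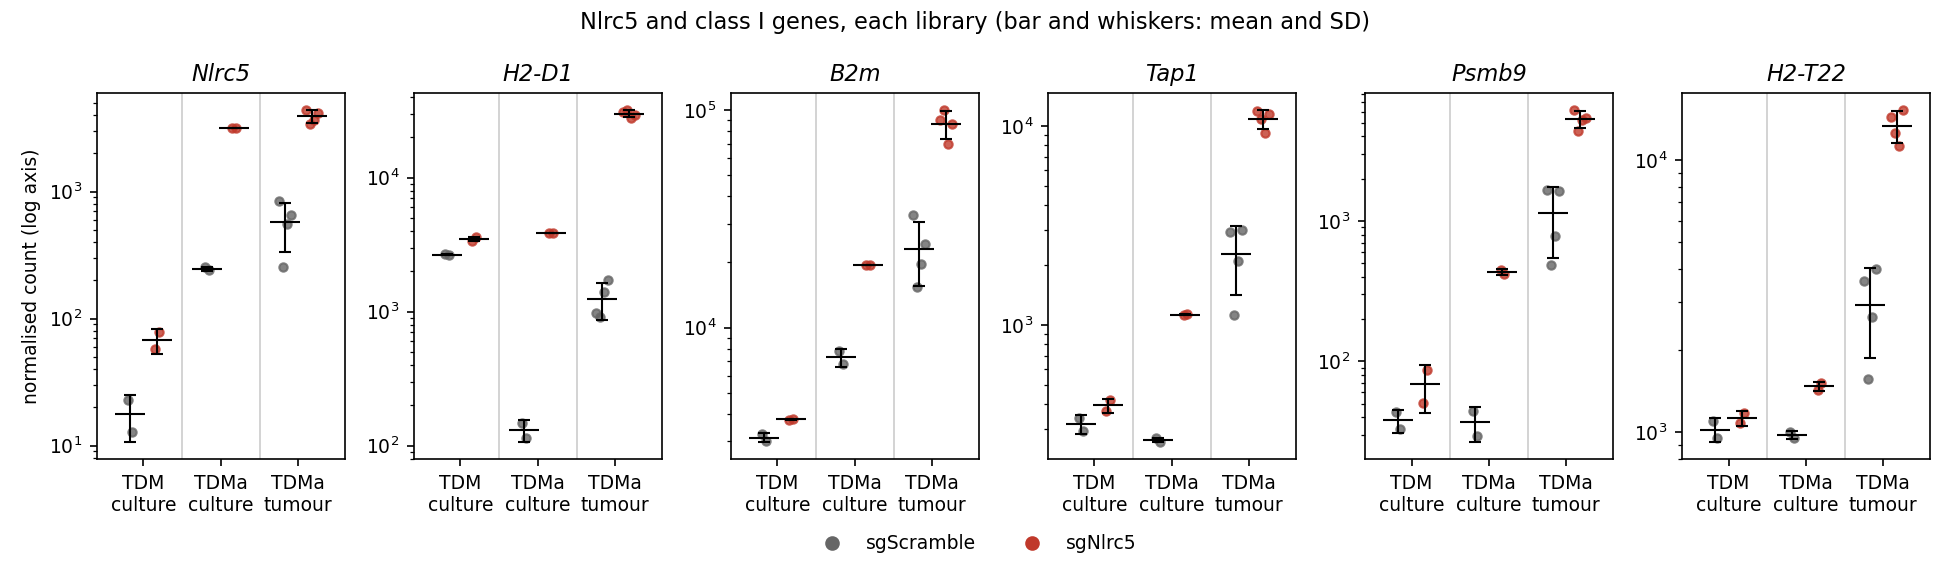
Normalised counts of Nlrc5 and 5 class I genes in each library (log axis), with the mean and SD of each group. In TDMa culture H2-D1 lay between 113 and 148 with sgScramble and between 3835 and 3847 with sgNlrc5, and in tumours between 911 and 1732 and between 27621 and 31900.

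The first comparison asked what the Nlrc5 guide did in cultured TDM cells. H2-D1 (ENSMUSG00000073411), a class I heavy chain, rose from 2668 to 3485 normalised counts, by log2 0.38 ± 0.050 (limma adjusted p = 6.4e-04). B2m (ENSMUSG00000060802), the class I light chain, rose by 0.28 ± 0.050 (adjusted p = 0.012), though not without sgScramble replicate 2 (0.23, adjusted p = 0.23). Without the intensity trend neither passed (adjusted p = 0.37 for H2-D1 and 0.52 for B2m). Other class I genes did not pass: the peptide transporter gene Tap1 was at 0.31 ± 0.11 (adjusted p = 0.40), the immunoproteasome gene Psmb9 at 0.80 ± 0.29 (adjusted p = 0.40), and H2-T24 at -0.55 ± 0.37 (adjusted p = 0.71). The class I heavy chain list had 2 of 6 members higher over all genes and 3 adjusted over the list alone (median 0.33, camera adjusted p = 8.6e-05). Its adjusted p = 0.54 with an estimated correlation. Among class I genes reported to depend on NLRC5, 2 of 7 rose over all genes and 5 adjusted over the list alone (median 0.38, camera adjusted p = 2.1e-08, adjusted p = 0.45 with an estimated correlation).

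Larger changes in TDM culture were in few genes. Tuba3b, a testis-enriched tubulin, rose from 61.5 to 984 normalised counts, by log2 3.98 ± 0.12 (adjusted p = 3.4e-12). Lncenc1, a long noncoding RNA of embryonic stem cells, rose by 2.69, Rlbp1, a retinaldehyde-binding protein, by 1.82, and Ccdc40, needed for motile cilia, by 1.81. Ulbp1, a ligand of the natural killer receptor NKG2D, rose by 1.70, Ctag2l1, of a cancer-testis antigen family, by 1.44, and the cation channel gene Trpv2 by 1.33. Tex19.1, a germline gene, fell from 330 to 85.5 normalised counts, a log2 change of -1.94 ± 0.14 (adjusted p = 8.2e-07). Thoc2l, related to an mRNA export factor, changed by -1.26, Smtnl2 by -0.78, Xylt1, which starts glycosaminoglycan chains, by -0.66, and the cilium gene Cfap54 by -0.53. Without the intensity trend Tuba3b still passed, while the other 11 genes of this paragraph had adjusted p between 0.059 and 0.48. Calls also ended for Ulbp1 without sgNlrc5 replicate 1 (adjusted p = 0.15), Ctag2l1 without sgNlrc5 replicate 1 or 2 (0.092, 0.052), Cfap54 without sgScramble replicate 1 or sgNlrc5 replicate 1 (0.12, 0.053), Smtnl2 without sgScramble replicate 2 or sgNlrc5 replicate 1 (0.21, 0.25) and Xylt1 without sgScramble replicate 1 or 2 or sgNlrc5 replicate 1 (0.13, 0.063, 0.14). Smtnl2 and Xylt1 also did not pass with quantile normalisation (0.11, 0.072), nor Smtnl2 without a filter on low values (0.055) or with voom (0.062).

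Hypoxia and glycolysis genes were lower with sgNlrc5 in TDM culture (median -0.13, camera adjusted p = 6.3e-09, adjusted p = 0.45 with an estimated correlation). Of 22 members, 2 fell over all genes: Bnip3, a mitophagy receptor, at -0.63 and Ero1a, an oxidase of the endoplasmic reticulum, at -0.32. Adjusted over the list alone, 7 were lower and 1 higher. Methylation-silenced germline genes had 2 of 8 members higher, Tuba3b and Tex101 (0.41, from 4031 to 5375 normalised counts), and Tex19.1 lower, and the same counts adjusted over the list alone. That list's camera adjusted p was 0.0021, with adjusted p = 0.54 with an estimated correlation. Imprinted genes were lower (median -0.16, camera adjusted p = 0.0016, adjusted p = 0.45 with an estimated correlation), with H19, an imprinted noncoding RNA, the 1 of 10 that passed (-0.80, from 272 to 156, adjusted p = 0.0069). Adjusted over the list alone, 3 imprinted genes were lower. Fibroblast genes were lower (median -0.24, camera adjusted p = 0.0021, adjusted p = 0.54 with an estimated correlation), with Col5a1, a collagen V chain, at -0.50 as the 1 of 5 that fell and 2 adjusted over the list alone. Calls ended for Bnip3 without sgNlrc5 replicate 2 (-0.41, adjusted p = 0.069) and with quantile normalisation (adjusted p = 0.12), Ero1a without sgScramble replicate 2 (-0.24, adjusted p = 0.15) and the fibroblast list without sgNlrc5 replicate 1 (median 0.044, adjusted p = 0.16). Without the intensity trend Tuba3b alone of the genes in this paragraph passed, with adjusted p of 0.059 for Tex19.1, 0.16 for H19, 0.27 for Col5a1, 0.32 for Tex101 and 0.58 for Bnip3 and Ero1a.

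Type I interferon genes had a median of 0.21 in TDM culture (camera adjusted p = 3.4e-04, adjusted p = 0.72 with an estimated correlation), with 0 of 26 members past the limma test, over all genes or adjusted over the list alone. Usp18, which restrains interferon signalling, stood at 0.75 ± 0.24 (adjusted p = 0.33), and passed without sgScramble replicate 1 (0.99), without sgNlrc5 replicate 1 (1.31) and with the replicate number as a block (adjusted p = 0.011). The interferon gamma list had a median of 0.27 (camera adjusted p = 0.0069, adjusted p = 0.72 with an estimated correlation), with 0 of 16 members called and 1 adjusted over the list alone. Both rested on sgNlrc5 replicate 2: without it the medians were -0.10 and 0.00040. The interferon gamma call ended at a mean of at least 50 (adjusted p = 0.086). The p53 target list (median 0.082, camera adjusted p = 0.0016), cholesterol synthesis (0.094, 0.015) and proliferation (0.038, 0.023) were called higher with 0 members past the test over all genes or adjusted over the list alone. Each had adjusted p = 0.45 with an estimated correlation. The cholesterol call ended without sgScramble replicate 1 or sgNlrc5 replicate 1 (0.14, 0.062), and the proliferation call without sgScramble replicate 1 or 2 (0.076, 0.23) or the intensity trend (0.14).

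In total 62 of 11989 genes passed in TDM culture, 34 higher and 28 lower, and 19 of them changed more than 2-fold. The count was 1084 at an unadjusted p under 0.05. It was 2 without the intensity trend and 99 without sgScramble replicate 1. The balance of directions rested on single libraries: 59 were higher and 87 lower without sgNlrc5 replicate 2, and 44 and 18 without sgNlrc5 replicate 1.

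The second comparison asked the same of cultured TDMa cells, where class I genes rose more. H2-D1 rose from 131 to 3841 normalised counts, by log2 4.88 ± 0.093 (limma adjusted p = 2.7e-17). In TDM it had reached 3485, so its larger rise lay mainly in a lower sgScramble level, 131 against 2668. Tap1 and Psmb9 instead started at similar levels, 264 and 36.7 against 318 and 38.0 in TDM. Each line was normalised alone, so these levels compare only roughly. H2-M3, which presents formylated peptides, rose by 3.72 ± 0.51, Psmb9 by 3.56 ± 0.19, Tap1 by 2.09 ± 0.076 and B2m by 1.41 ± 0.042, from 7287 to 19345 normalised counts. H2-T22, a nonclassical class I gene, rose by 0.59 ± 0.055, while H2-T24 stood at 0.21 ± 0.26 (adjusted p = 0.59). The H2 genes belong to a multigene family with near-identical stretches, so their separate values are uncertain, and H2-K1 and H2-T23 in culture were not analysed here. Of 6 reported NLRC5-dependent genes, 6 rose over all genes and 6 adjusted over the list alone (median 2.82, camera adjusted p = 8.5e-11, adjusted p = 0.29 with an estimated correlation). Of 5 heavy chain and B2m members, 4 rose by either count (median 1.41, camera adjusted p = 2.7e-06, adjusted p = 0.29 with an estimated correlation). H2-M3 had 20.1 and 2.85 normalised counts in the sgScramble replicates 1 and 2, and its rise was 4.94 without the former and 2.49 without the latter. Without the intensity trend H2-M3 had an adjusted p of 0.085, and the other class I calls of this paragraph held.

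Interferon-stimulated genes were lower with sgNlrc5 in TDMa culture. Of 23 type I interferon genes, 21 fell and 0 rose, with 22 lower adjusted over the list alone (median -1.63, camera adjusted p = 8.4e-14, adjusted p = 0.29 with an estimated correlation). Ddx58, the RNA sensor RIG-I, fell from 1131 to 296 normalised counts (-1.92 ± 0.098), and Oas1a, an antiviral oligoadenylate synthetase, from 157 to 8.86 (-3.95 ± 0.31). Ifit3 and Rtp4, both interferon-induced, changed by -1.81 and -2.79. Of 13 interferon gamma response genes, 11 fell over all genes and 11 adjusted over the list alone (median -1.72, camera adjusted p = 8.5e-11, adjusted p = 0.29 with an estimated correlation). The chemokine gene Cxcl10 fell from 400 to 69.6 normalised counts (-2.51 ± 0.15), the immunity-related GTPase genes Irgm1 and Irgm2 changed by -1.69 and -2.62, and Gbp3, encoding a guanylate-binding protein, by -3.40. NF-kB and chemokine genes were lower in 6 of 7 by either count, including Csf1 at -0.90, Nfkbia at -1.08 and Cxcl1 at -4.33 (median -0.90, camera adjusted p = 8.3e-06, adjusted p = 0.29 with an estimated correlation). The T cell chemokine gene Ccl5 changed by -2.23 ± 0.16, from 300 to 63.0.

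Pigment cell genes rose in TDMa culture. Of 18 melanocyte lineage genes, 14 rose and 0 fell, with 15 higher adjusted over the list alone (median 0.43, camera adjusted p = 1.4e-13, adjusted p = 0.26 with an estimated correlation). The melanosome genes Pmel, Rab38, Tyrp1 and Dct rose by 0.64, 0.84, 0.69 and 0.42. Cholesterol synthesis genes rose in 15 of 18 by either count (median 0.47, camera adjusted p = 2.1e-10, adjusted p = 0.26 with an estimated correlation), with Insig1 at 1.06 and the regulator Srebf2 at 0.53. Hypoxia and glycolysis genes rose in 15 of 21 and fell in 1, with 16 higher and 1 lower adjusted over the list alone (median 0.46, camera adjusted p = 1.6e-12, adjusted p = 0.29 with an estimated correlation). The kinase gene Pdk1, whose product inhibits pyruvate dehydrogenase, rose by 1.47, and the glycolytic genes Pgk1, Aldoa and Ldha by 0.73, 0.61 and 0.53. Genes of the unfolded protein and integrated stress response rose in 10 of 20 and fell in 3, with 11 and 3 adjusted over the list alone (median 0.19, camera adjusted p = 0.0029, adjusted p = 0.29 with an estimated correlation). The chaperone members Hsp90b1 and Hspa5 rose by 0.57 and 0.49, and the 3 that fell, named after their values were seen, were Nupr1 (-1.46), Slc7a11 (-1.05) and Asns (-0.23).

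Several genes in TDMa culture went to or near 0 with sgNlrc5. Itpripl2 fell from 898 to 9.50 normalised counts (-6.44 ± 0.20). Gpm6b, a membrane glycoprotein, fell from 218 to 1.61 normalised counts, resting on 3 reads, with a ratio between 0.00147 and 0.0211. Echdc2 and the actin-capping gene Tmod2 went from 73.5 and 73.4 to 0, each at least 47.1-fold lower, and Lysmd2 from 54.8 to 0, at least 35.1-fold lower. The ubiquitin ligase gene Neurl3 (ratio 0.00193 to 0.0277), the sulfhydryl oxidase gene Qsox1 (0.000145 to 0.0326) and the desmosome gene Pkp2 (0.00302 to 0.0436) rested on 1 to 3 reads with sgNlrc5. Rhox5, a germline homeobox gene, fell from 2173 to 150 (-3.85 ± 0.076). In the other direction, Wfikkn2, an extracellular inhibitor of growth factors, rose from 9.55 to 195 normalised counts (4.32 ± 0.32), Prxl2a by 4.42, and Tmem144 from 3 reads to 117 (ratio 14.2 to 209).

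Fibroblast genes were lower in 4 of 6 and higher in 1 by either count (median -0.69, camera adjusted p = 0.030, adjusted p = 0.33 with an estimated correlation), with the collagen genes Col5a1 at -0.99 and Col1a1 at -1.32. That call ended with quantile normalisation (adjusted p = 0.068) and equal sums (adjusted p = 0.056). Skeletal muscle genes were lower in 3 of 4 and in 4 adjusted over the list alone, among them Des at -0.78 (median -0.90, camera adjusted p = 0.040, adjusted p = 0.33 with an estimated correlation), and that call ended with the same scalings (0.081 and 0.073) and with the replicate number as a block (0.085). Class I antigen processing genes went both ways, 5 higher and 6 lower of 16, with 5 and 8 adjusted over the list alone (camera adjusted p = 0.99). The chaperone gene Calr rose by 0.56 and Pdia3 by 0.43. Germline genes were not called (camera adjusted p = 0.78), with 3 higher and 1 lower of 5 by either count, a median of 0.24 and a mean of -0.55. Genomic neighbours of Nlrc5 were not called (median -0.061, camera adjusted p = 0.78), with 1 higher and 1 lower of 17 over all genes, Herpud1 at 0.27 and Gnao1 at -0.17, and 1 higher adjusted over the list alone. Gnao1 did not pass without any 1 of the 4 libraries (adjusted p from 0.079 to 0.15), nor Herpud1 without sgScramble replicate 2 (0.052), and neither passed without the intensity trend (0.11 and 0.073).

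In total 4156 of 12138 genes passed in TDMa culture, 2100 higher and 2056 lower, and 538 of them changed more than 2-fold, 148 higher and 390 lower. With equal sums of normalised counts the split was 1643 higher and 2587 lower, 38.8% higher against 50.5%. The count was 1581 without the intensity trend, where 32 of the 122 genes picked by the naming rule lost their call (H2-M3, Herpud1 and Gnao1 among those given above), 2512 without sgScramble replicate 1 and 2642 without sgScramble replicate 2.

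The third comparison asked how TDMa tumours with sgNlrc5 differed from those with sgScramble, and class I genes rose throughout. H2-D1 rose from 1253 ± 385 to 29997 ± 1868 normalised counts (SD, n = 4 and 4), by log2 4.63 ± 0.17 (limma adjusted p = 7.4e-08). H2-T23, the Qa-1 gene, rose by 4.64 ± 0.44, from 465 to 9486, and H2-K1, the other classical heavy chain of this strain, by 2.35 ± 0.21, from 768 to 3816. B2m rose by 1.95 ± 0.22, Tap1 by 2.34 ± 0.25, Psmb9 by 2.39 ± 0.32 and H2-T22 by 2.26 ± 0.24. The remaining class I genes H2-Q4, H2-Q6, H2-Q7, H2-M3, H2-T10, H2-K2 and H2-T24 rose by between 1.52 and 2.86. All 12 heavy chain and B2m members rose by either count (median 2.48, camera adjusted p = 1.5e-10, adjusted p = 0.31 with an estimated correlation), as did all 11 reported NLRC5-dependent genes (median 2.39, camera adjusted p = 1.5e-10, adjusted p = 0.31 with an estimated correlation). Class I antigen processing rose in 9 of 17 and fell in 1 by either count, with Psmb8 at 2.83, Psmb9 at 2.39 and Tap1 at 2.34 (median 0.35, camera adjusted p = 0.0077, adjusted p = 0.43 with an estimated correlation).

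Markers of lymphocytes were higher in the same sgNlrc5 tumours. Lat, Havcr2 and Ccl5, named below, were also expressed in TDMa culture, which holds no host cells. Thy1 is also on the fibroblast list. Of 23 T cell genes, 21 rose and 0 fell, with 22 higher adjusted over the list alone (median 2.64, camera adjusted p = 9.1e-10, adjusted p = 0.31 with an estimated correlation). The coreceptor gene Cd8a rose from 14.5 ± 3.03 to 174 ± 100 normalised counts (3.36 ± 0.34), with 317 and 173 in sgNlrc5 replicates 1 and 2 and 97.6 and 111 in replicates 3 and 4. The receptor subunit gene Cd3g rose by 3.30, the adaptor gene Lat by 2.33 and Thy1 by 2.12. Cytotoxic effector genes rose in 9 of 16 and in 11 adjusted over the list alone, with Nkg7 at 2.78 and Ccl5 at 2.42 (median 1.97, camera adjusted p = 2.4e-05, adjusted p = 0.40 with an estimated correlation). Checkpoint genes rose in 10 of 14 and in 11 adjusted over the list alone (median 1.48, camera adjusted p = 2.4e-05, adjusted p = 0.31 with an estimated correlation). Among them Pdcd1, encoding PD-1, rose from 5.94 to 83.1 (3.52 ± 0.43), Lag3 by 2.63 and Havcr2, encoding TIM-3, by 1.74. NK cell genes rose in 5 of 6 by either count, with Il2rb at 2.46 (median 2.45, camera adjusted p = 0.0011, adjusted p = 0.31 with an estimated correlation), and B cell genes in 3 of 4, with the immunoglobulin gene Igkc at 2.46 (median 1.60, camera adjusted p = 0.016, adjusted p = 0.31 with an estimated correlation).

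Myeloid and stromal markers moved too. Cd68 and Postn, named below, were also expressed in TDMa culture, which holds no host cells. Macrophage genes rose in 17 of 20 by either count (median 1.63, camera adjusted p = 1.5e-10, adjusted p = 0.31 with an estimated correlation), with Cd68 rising from 1142 to 4558 (1.98 ± 0.12), the complement gene C1qc by 1.98 and Adgre1, encoding F4/80, by 2.13. MHC class II genes rose in 8 of 8 by either count, with H2-Eb1 at 2.98, the invariant chain gene Cd74 at 2.95 and H2-Ab1 at 2.67 (median 2.50, camera adjusted p = 2.3e-05, adjusted p = 0.40 with an estimated correlation). Dendritic cell genes rose in 4 of 9 and fell in 1, with 5 and 1 adjusted over the list alone, and Itgax at 1.86 (median 0.94, camera adjusted p = 0.0497, adjusted p = 0.40 with an estimated correlation). That call ended with quantile normalisation (adjusted p = 0.082) and without sgScramble replicate 2 (adjusted p = 0.061) or 3 (0.065) or sgNlrc5 replicate 1 (0.062), and with 4 other settings. Fibroblast genes rose in 8 of 12 and fell in 1, with 9 and 1 adjusted over the list alone (median 1.00, camera adjusted p = 0.0022, adjusted p = 0.31 with an estimated correlation). The matrix crosslinker gene Loxl1 rose by 3.46 and Postn by 1.80, and Pdgfra stood at -1.35. Endothelial genes were not called (median 0.56, 1 of 9 higher by either count, camera adjusted p = 0.17), nor were erythroid genes (median -0.98, 2 of 7 lower by either count, camera adjusted p = 0.068). The erythroid list was called lower in 6 alternatives (adjusted p from 0.021 to 0.049), and the endothelial list higher without sgScramble replicate 2 (adjusted p = 0.031).

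Interferon response genes rose in tumours. Of 29 type I interferon genes, 25 rose and 0 fell, with 27 higher adjusted over the list alone (median 1.14, camera adjusted p = 2.3e-09, adjusted p = 0.41 with an estimated correlation). Oas2 rose by 2.61 ± 0.30, Xaf1 by 1.25 and Ddx58 by 0.94. Of 26 interferon gamma response genes, 19 rose and 22 adjusted over the list alone (median 1.41, camera adjusted p = 4.1e-07, adjusted p = 0.43 with an estimated correlation). The transcription factor gene Irf8 rose by 1.67, the chemokine gene Cxcl9 by 1.60, and Cd274, encoding PD-L1, by 1.58. NF-kB and chemokine genes rose in 9 of 15 and fell in 2, with 12 and 2 adjusted over the list alone, among them Vcam1 at 1.80 and Csf1 at 1.49 (median 1.25, camera adjusted p = 0.0028, adjusted p = 0.40 with an estimated correlation). Other NLR genes rose in 6 of 11 and in 7 adjusted over the list alone, with the class II transactivator gene Ciita at 2.03 and the inflammasome gene Nlrp3 at 1.34 (median 0.92, camera adjusted p = 0.013, adjusted p = 0.43 with an estimated correlation). The NLR call ended at a mean of at least 50 (adjusted p = 0.078) and with quantile normalisation (adjusted p = 0.054).

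Pigmentation, proliferation and metabolic genes also moved in the tumours. Melanocyte lineage genes rose in 11 of 20 and fell in 3 by either count (median 0.41, camera adjusted p = 0.0042, adjusted p = 0.41 with an estimated correlation), with the pigmentation genes Oca2, Trpm1 and Mc1r at 1.57, 1.02 and 0.79. Proliferation genes fell in 11 of 23 and rose in 1, with 12 and 1 adjusted over the list alone (median -0.33, camera adjusted p = 4.5e-04, adjusted p = 0.47 with an estimated correlation). The cell cycle genes Mki67 and Cenpf changed by -1.42 and -1.28. Cholesterol synthesis genes fell in 6 of 19 by either count (median -0.30, camera adjusted p = 0.0016, adjusted p = 0.53 with an estimated correlation), with Stard4 at -1.16 and Idi1 at -0.98. DNA methylation genes fell in 6 of 14 by either count (median -0.29, camera adjusted p = 0.0045, adjusted p = 0.40 with an estimated correlation), and the demethylation enzyme genes Tet1 and Tet3 changed by -1.10 and -0.76.

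The largest single rises outside class I were Cox8b, a cytochrome oxidase subunit, by 4.19, Hsd11b1, which regenerates active glucocorticoid, by 4.16 ± 0.36 (25.2 to 513 normalised counts), the efflux pump gene Abcc2 by 3.94 and the germ cell gene Tex101 by 3.92. Hcar1, a lactate receptor, and the olfactory receptor gene Olfr99 rose by 3.88 and 3.79. The largest falls were Npnt, encoding the matrix protein nephronectin, from 172 to 5.22 normalised counts (-5.04 ± 0.39), Capn6 at -4.51, the imprinted noncoding RNA Peg13 at -4.44, the protocadherin gene Pcdhb2 at -3.51, Igfn1 at -3.36 and Cer1, a secreted antagonist of Nodal and BMP, at -3.31. Fndc3c1 and the kinase gene Pak3 changed by -3.21 and -3.13. In total 5268 of 13385 genes passed in tumours, 2635 higher and 2633 lower, and 1343 changed more than 2-fold, 1080 higher and 263 lower. Tumour libraries hold RNA of every cell type present, so a change can lie in the melanoma cells, in other cells or in their shares.

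The difference between the lines was tested directly. In TDMa culture the sgNlrc5 effect exceeded that in TDM culture for Nlrc5 by log2 1.75 ± 0.26 (limma interaction, adjusted p = 1.4e-05), H2-D1 by 4.49 ± 0.11, Psmb9 by 2.76 ± 0.35, Tap1 by 1.78 ± 0.14 and B2m by 1.13 ± 0.068. The difference was 0.76 ± 0.46 for H2-T24 (adjusted p = 0.26). For H2-D1 the lines differed mainly in the sgScramble level, 131 in TDMa against 2668 in TDM, while sgNlrc5 levels were 3841 and 3485. The calls of H2-M3 (3.33) and H2-T22 (0.45) ended without the intensity trend (adjusted p = 0.11 and 0.077). Interferon genes differed the other way, with medians of -1.66 for type I and -1.92 for interferon gamma genes (camera adjusted p = 3.1e-17 and 3.5e-13, adjusted p = 0.19 and 0.13 with an estimated correlation). Of these, 18 of 23 and 11 of 13 were more negative in TDMa, and 20 and 12 adjusted over the list alone. Melanocyte and cholesterol genes were more positive in TDMa (medians 0.46 and 0.43, camera adjusted p = 3.1e-12 and 1.8e-07), and these calls held with an estimated correlation (adjusted p = 0.049 for both). In all, 2610 of 11492 genes differed, 1374 more positive and 1236 more negative in TDMa, and 1186 did without the intensity trend. With equal sums of normalised counts the balance turned, to 1099 more positive and 1477 more negative. Of genes tested in both lines, 11 were higher in both against 4.13 for independent sets (odds ratio 4.21, Fisher's exact p = 9.8e-04) and 5 went from higher to lower. Lower in both were 8 against 3.94 (odds ratio 2.55, Fisher's exact p = 0.046), while 14 were lower in TDM and higher in TDMa. The call for lower genes ended with equal sums (odds ratio 2.08, Fisher's exact p = 0.073) and with 3 other settings. Opposite directions were not set against independent sets, so these overlaps do not show that the lines shared directions.

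The difference between TDMa tumours and TDMa culture was tested the same way. H2-T22 and H2-T24 rose more in tumours, by 1.67 ± 0.26 and 1.31 ± 0.36 (limma interaction, adjusted p = 1.2e-04 and 0.0092). Psmb9 rose less, by -1.17 ± 0.39 (adjusted p = 0.027), which did not pass with a pseudocount of 10 (adjusted p = 0.067) without the intensity trend (0.081) or without any 1 of 5 libraries (0.059 to 0.12). With 1 spread for both tables the adjusted p was 0.11 for Psmb9 and 0.052 for H2-T24. Nlrc5 differed by -0.79 ± 0.30 (adjusted p = 0.052), B2m by 0.54 ± 0.23 (adjusted p = 0.077) and H2-D1 by -0.25 ± 0.22 (adjusted p = 0.40). Nlrc5 passed at a mean of at least 50 (adjusted p = 0.041), with quantile normalisation or equal sums (0.049 for both), with the block (0.012) and without tumour sgScramble replicate 2 (-1.13, 5.2e-05) or tumour sgNlrc5 replicate 1 (-0.84, 0.049). B2m passed without tumour sgScramble replicate 1 (0.73, adjusted p = 0.0092) or tumour sgNlrc5 replicate 3 (0.64, 0.035). All 23 type I interferon genes and all 13 interferon gamma genes tested in both were more positive in tumours and passed, over all genes and adjusted over the list alone. Their median differences were 2.22 and 2.88 (camera adjusted p = 4.3e-18 and 2.8e-11, adjusted p = 0.31 for both with an estimated correlation). Cholesterol synthesis genes were more negative in tumours in 15 of 18 by either count (median -0.83, camera adjusted p = 3.2e-07, adjusted p = 0.31 with an estimated correlation). In all, 4311 of 11782 genes differed, 1771 more positive and 2540 more negative in tumours, and 2799 did with 1 spread for both tables. Lower in both were 577 genes against 430 for independent sets (odds ratio 1.63, Fisher's exact p = 9.4e-18), which was not past the threshold without the intensity trend (odds ratio 1.16, p = 0.093). Higher in both were 361 against 331 (odds ratio 1.13, Fisher's exact p = 0.051), while 516 were higher in culture and lower in tumours and 409 the reverse. Here too opposite directions were not set against independent sets, so neither overlap shows shared direction.

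**Figure D2:**
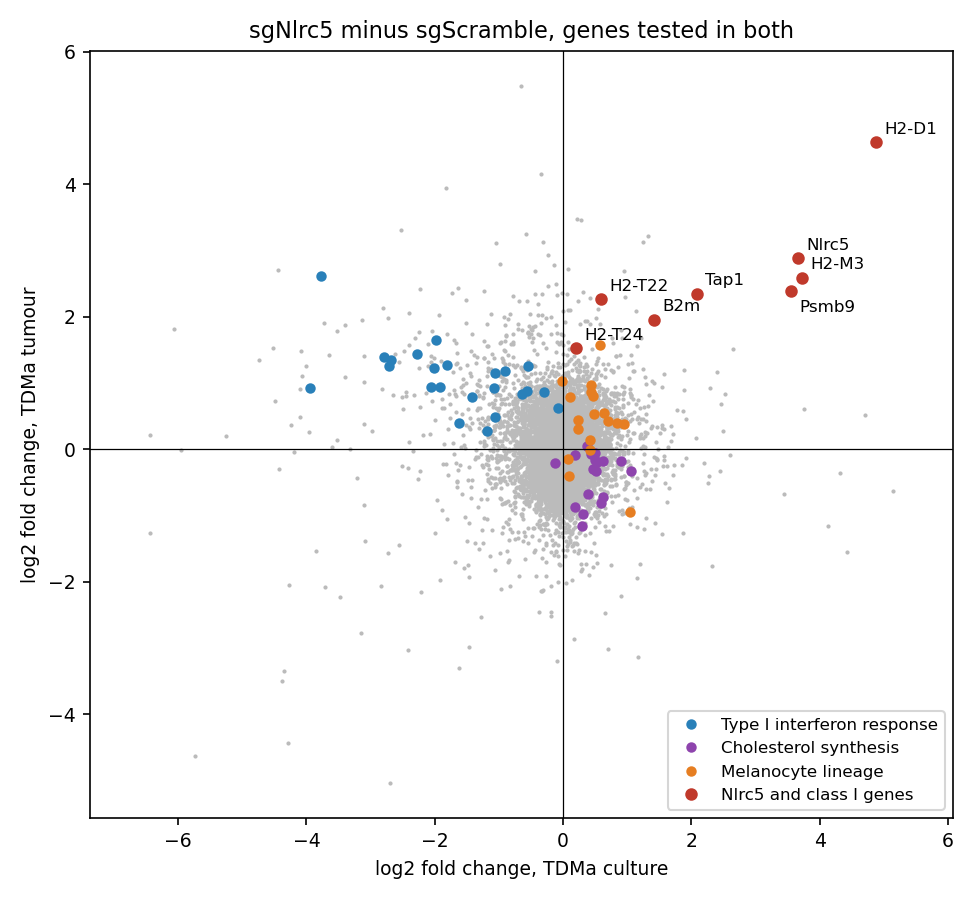
Log2 fold change (sgNlrc5 minus sgScramble) in TDMa culture (horizontal) and TDMa tumours (vertical) for genes tested in both, with Nlrc5, class I genes and 3 gene lists coloured. H2-D1 lay at 4.88 and 4.63, and type I interferon genes lay to the left of 0 and above it.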

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

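The regrouping counts for genes and for lists were planned before the data were examined, while the splits for single lists and the tests of the 3 patterns weighed below were chosen only after the results were seen. A library was singled out where its gap to the nearest library of its group took an unusually large share of the group's range, which happens by chance in about 1 group of 20. That held for 14 of 304 gene groups (4.61%), 2 of 66 list groups (3.03%) and 1 of 2 groups for depth, all in tumours, since groups of 2 could not be judged. That rule finds single libraries only. Named after the values were seen, the sgNlrc5 tumours formed pairs: the chi-square per gene of recovered reads was 9.33 between replicates 3 and 4, 19.6 between 1 and 2, and 30.4 to 49.1 across, against 9.90 to 23.2 among sgScramble tumours. The 10 most abundant genes took 13.3% and 14.1% of reads in replicates 1 and 2 and 9.88% and 10.2% in 3 and 4. The cause was not tested.

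With sgNlrc5, replicate 1 stood apart for Tdrd9 (gap share 0.879, log2 3.91 against 5.62 to 5.86), Eng (0.944, 11.76 against 12.07 to 12.09) and Hsp90aa1 (0.880, 13.27 against 13.59 to 13.64). Replicate 3 stood apart for Pak3 (0.909, 4.72 against 5.29 to 5.35), Havcr2 (0.910, 6.47 against 6.83 to 6.86), the erythroid list (0.831, mean log2 7.54 against 6.55 to 6.72) and recovered reads (0.873, 15898495 against 14299220 to 14502670). Replicate 4 stood apart for Ddx58 (0.847, 10.64 against 10.24 to 10.30), Fabp4 (0.911, 6.35 against 6.67 to 6.70) and Vcam1 (0.831, 7.61 against 8.55 to 8.74). With sgScramble, replicate 1 stood apart for Mc1r (0.892, 11.20 against 10.87 to 10.91) and mt-Nd3 (0.930, 2.15 against 4.46 to 4.63), and replicate 2 for Nod1 (0.869, 8.80 against 9.32 to 9.40). Replicate 4 of sgScramble stood apart for Igf2r (0.879, 11.45 against 11.85 to 11.91), Itgax (0.880, 5.84 against 5.61 to 5.63), Ccl2 (0.847, 8.70 against 7.31 to 7.52) and the hypoxia list (0.930, mean log2 12.09 against 11.88 to 11.89).

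Differences between groups past the limma interaction test counted 2610 genes between the lines in culture and 4311 between TDMa tumours and culture. Between the lines the class I genes that differed were Nlrc5 (1.75), H2-D1 (4.49), H2-M3 (3.33), Psmb9 (2.76), Tap1 (1.78), B2m (1.13) and H2-T22 (0.45). The lists that differed by camera were class I heavy chains (median 1.13), NLRC5-dependent genes (2.27), type I interferon (-1.66), interferon gamma (-1.92), hypoxia (0.67), melanocyte lineage (0.46), cholesterol (0.43), NF-kB (-0.63), stress response (0.26) and p53 targets (-0.19). With an estimated correlation their adjusted p ran from 0.049 for melanocyte lineage and cholesterol to 0.20 for stress response. Between tumours and culture the genes were H2-T22 (1.67), H2-T24 (1.31) and Psmb9 (-1.17). The lists were type I interferon (2.22), interferon gamma (2.88), NF-kB (1.05), macrophages (0.98), fibroblasts (1.28), other NLR genes (1.54), immediate early genes (0.52), cholesterol (-0.83), hypoxia (-0.55), proliferation (-0.38) and DNA methylation (-0.42). With an estimated correlation their adjusted p ran from 0.23 for macrophages and NF-kB to 0.53 for proliferation. The immediate early call ended in 12 alternatives (adjusted p from 0.051 to 0.094), 9 of them with 1 library left out.

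Of the 35 ways to split the 8 tumours into groups of 4, the real one called 5268 genes and the highest other called 0. That is 1 of 35, the smallest share these splits can give, so it argues against chance without excluding it. For the number of called lists, 3 of the 35 splits gave as many, with 20 in the real split and 22 in the highest other. The count of lists therefore does not argue against chance. Among single lists, the real split alone reached its own median, 1 of 35, for class I (2.48, highest other 1.59), T cells (2.64, 1.99), macrophages (1.63, 1.13) and type I interferon (1.14, 1.07). Other splits matched the medians of interferon gamma (2 of 35, 1.41 against a highest other of 1.43), antigen processing (9 of 35, 0.35 against 0.57), proliferation (4 of 35) and cholesterol (6 of 35). These 4 therefore do not argue against chance. Nor does 1 of 35 exclude chance for the other lists, and the margin for type I interferon was small.

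The first pattern was the lower interferon genes in TDMa culture with sgNlrc5. Under 2 other scalings the highest type I median was -1.57 (camera adjusted p up to 8.3e-12), and with 1 library left out it ran from -1.76 to -1.43, which argues against scaling and against a single library. As deposited the list had adjusted p = 0.29 with an estimated correlation. A difference between the transduced TDMa lines other than the guide could give the same pattern. In TDM culture the median was 0.21, but Nlrc5 there reached 68.0 normalised counts against 3144, so the guide's effect and a line difference cannot be told apart.

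The second pattern was 70 genes more than 8-fold lower in TDMa culture with sgNlrc5, against 12 higher. No technical explanation was tested for it. A stable loss of expression in the sgNlrc5 line may be one source. Of 44 of these genes tested in tumours, 10 were lower there and 17 higher. Among all 13385 genes tested in tumours, 2633 were lower and 2635 higher. The 10 lie near that general share, so they do not by themselves argue for such a loss. Host cells also contribute reads to tumours, so this stays open.

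The third pattern was the higher immune lists in sgNlrc5 tumours. A lower melanoma share alone would raise all host cells alike. Among markers listed in neither culture, the T cell mean rose more than the erythroid mean by 3.59 (exact Wilcoxon over the 8 tumours, p = 0.029). That is the smallest p this test can give. The T cell mean rose more than the endothelial mean by 1.72 (exact Wilcoxon over the 8 tumours, p = 0.20). The erythroid list itself had a median of -0.98, so the first gap may partly reflect lower erythroid genes. The second gap was not past the threshold. A lower share would also lower melanocyte lineage genes, yet 11 of 20 rose in these tumours and 3 fell (median 0.41). They rose in TDMa culture as well (median 0.43), so a rise within melanoma cells could hide a lower share. A lower share as the only source therefore stays open. The 14 class I genes rose by a median of 2.38 in these tumours against 2.64 for the T cell list. Cultured TDMa cells also expressed class I genes, so comparing these medians cannot place the class I rise. More infiltrating cells may be a source of it. In TDMa culture, which holds no host cells, 6 of 6 reported NLRC5-dependent class I genes rose (median 2.82). That argues against infiltrating cells as the only source for these 6. The shares of infiltrating cells and melanoma cells in the tumour rise were not separated.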

How the results depend on the processing

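All alternatives were chosen before the data were examined. In TDM culture, where 62 genes passed, 2 did without the intensity trend, 122 with the replicate number as a block, and 62 to 146 with 1 library left out, the most without sgNlrc5 replicate 2. TDM Nlrc5 stayed at 1.91 without the trend (adjusted p = 0.38) and ran from 1.51 without sgScramble replicate 2 to 2.31 without sgScramble replicate 1. The TDM type I interferon median was -0.10 without sgNlrc5 replicate 2 and 0.60 without sgNlrc5 replicate 1, and the interferon gamma median 0.00040 and 0.65. In TDMa culture, where 4156 genes passed, 1581 did without the trend, and 2512 to 3335 with 1 library left out, the fewest without sgScramble replicate 1 and the most without sgNlrc5 replicate 2. TDMa Hsp90aa1 went from 0.15 to -0.023 with quantile normalisation (adjusted p = 0.72). The tumour count, 5268, ran from 4533 to 5880 over the alternatives and from 4336 to 5370 with 1 library left out. Voom called 59, 4256 and 5259 genes in the 3 comparisons. Fry's test of direction, which does not compare a list with the other genes, called no list in TDM culture (lowest adjusted p = 0.099). In TDMa culture its adjusted p was 0.0078 for class I heavy chains, higher, and 0.0083 for type I interferon, lower. In tumours both were higher, with fry adjusted p of 2.1e-04 and 0.023. Fry's mixed test, which ignores direction, did call lists in TDM culture. Germline genes had a mixed fry adjusted p of 0.0026 and class I heavy chains 0.049. Differences between the lines fell from 2610 to 1186 without the trend, and those between tumours and culture from 4311 to 2799 with 1 spread for both tables. The cause of these changes was not tested.

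The overlap of lower genes between the lines (odds ratio 2.55) was 2.52 without a filter, 1.82 with quantile normalisation, 2.08 with equal sums and 1.62 with the block, none past the threshold (Fisher's exact p from 0.069 to 0.41). The overlap of higher genes between TDMa culture and tumours (1.13) passed at 1.14 with a pseudocount of 0.5, 1.15 without a filter, 1.25 with quantile normalisation, 1.20 with equal sums and 1.42 without the trend. The overlap of lower genes was 1.16 without the trend (Fisher's exact p = 0.093).

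The replicate numbers did not pair the samples: within-number correlations were -0.024 in TDM culture, -0.015 in TDMa culture and -0.21, 0.11, -0.18 and -0.017 in tumours, where only replicate 2 correlated best with its own number. As a block they gave 4433 genes in TDMa culture, 4533 in tumours, 2508 between the lines and 3832 between tumours and culture. Recovered reads cover listed genes only, so genes under about 20 reads in culture and 40 in tumours could not be judged.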

Other observations

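The genes more than 8-fold lower in TDMa culture, Rhox5 among them, were counted in the second pattern, and the class I genes in the third. No other gene or list of this part was used by itself to test an explanation. Several lists were not called in tumours. Skeletal muscle genes rose in 3 of 6 by either count, with Des at 1.39 and the calcium pump gene Atp2a1 at 2.69 (median 1.05, camera adjusted p = 0.068), and that list was called without sgScramble replicate 1 (adjusted p = 0.034). Immediate early genes rose in 6 of 16 by either count, with Jun at 1.01 (median 0.34, camera adjusted p = 0.077), and that list was called in 4 alternatives (adjusted p from 0.0083 to 0.045). Heat shock genes rose in 2 of 12 and fell in 3, or 5 adjusted over the list alone, with Hsp90aa1 at -0.88 and Hspb1 at 1.02 (median -0.19, camera adjusted p = 0.34). Adipocyte genes rose in 1 of 4 and fell in 1, with 2 and 1 adjusted over the list alone, Pparg at 1.27 and Scd1 at -0.45 (median 0.74, camera adjusted p = 0.44). Mitochondrially encoded genes had 0 of 13 past the limma test by either count (median 0.23, camera adjusted p = 0.39), with mt-Co3 at 0.84 (adjusted p = 0.066). Neutrophils and keratinocytes had 2 tested members each and no list test, with the neutrophil gene Csf3r at 1.88 and the keratinocyte gene Sfn at 1.28 past the limma test, and Mmp8 at 0.88 (adjusted p = 0.19) and Dsp at 0.38 (adjusted p = 0.28) not. Sfn did not pass with quantile normalisation (adjusted p = 0.13), sample weights (0.056) or without any 1 of 5 libraries (0.062 to 0.093), nor Scd1 without the intensity trend (0.061) or any 1 of 4 libraries (0.053 to 0.070). Mmp8 and Dsp passed with sample weights (0.030 and 0.044), Mmp8 also without sgNlrc5 replicate 1 (0.019), and mt-Co3 without any 1 of 3 libraries (0.027 to 0.039).

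The stress response list in tumours went both ways, 4 higher and 6 lower of 21, or 4 and 7 adjusted over the list alone, with the amino acid synthesis genes Asns and Phgdh at -1.22 and -0.93 and Atf3 at 1.51. Its median was 0.062 and its mean -0.049 (camera adjusted p = 0.48). Germline genes in tumours had a median of -0.10 and a mean of 0.82 (camera adjusted p = 0.56), with Tex101 at 3.92 and Tuba3b at 3.34 among 3 of 8 higher and Rhox5 at -1.54 the 1 lower. Rhox5 did not pass without sgScramble replicate 4 (adjusted p = 0.063), sgNlrc5 replicate 2 (0.067), sgNlrc5 replicate 4 (0.066) or the intensity trend (0.073). Imprinted genes in tumours were not called (camera adjusted p = 0.44), with Peg10 at -2.12 the 1 of 7 that passed. In TDMa culture Peg10 changed by -0.97 and Plagl1 by 0.65, with 3 higher and 3 lower of 7 by either count, a median of 0.10, a mean of 0.018 and a camera direction of lower (adjusted p = 0.79). Macrophage genes in TDMa culture had a median of 0.21 and a mean of -0.33 (camera adjusted p = 0.33), with Cd68 at 0.52 and Lyz2 at -2.25. Antigen processing in TDMa culture had a median of -0.13 and a mean of 0.16.

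Of the 12 genes more than 8-fold higher in TDMa culture with sgNlrc5, 11 were tested in tumours. Nlrc5, H2-D1, H2-M3, Psmb9 and Aire were higher there, while Prxl2a (-1.55), Mfsd13a (-0.64) and Wfikkn2 (-0.37) were among those lower. Aire and Mfsd13a were named after their values were seen. Among genes more than 8-fold lower in culture, Peg13 (-4.28 and -4.44), Igfn1 (-4.34 and -3.36) and Pcdhb2 (-4.38 and -3.51) were lower in culture and tumours, while the antiviral gene Oas1a was lower in culture (-3.95) and higher in tumours (0.93).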
